A study of Mus musculus with 24 samples.

How the data were processed

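The study measured nuclear RNA of spinal cord astrocytes in mouse pups. Per the labels' protocols, the mice carried a tamoxifen-inducible Cre recombinase under the astrocyte gene Aldh1l1 and a Cre-dependent Sun1-GFP fusion protein, which marks the nuclear envelope. GFP-positive nuclei were sorted by flow cytometry from the dorsal horn of the lumbar spinal cord on the side of a hindpaw incision. RNA was isolated with a single-cell RNA kit and libraries were made with a low-input kit, 1 library per mouse. Incised pups had a hindpaw incision on postnatal day 3 (P3), and control pups, labelled naive, had anaesthesia with isoflurane alone. Tissue was taken 1, 7 or 21 days later, at P4, P10 or P24.

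The reads had been processed with STAR, Salmon and DESeq2 on the mouse build mm10, per the submitters' processing notes, which give no versions. The deposited tables hold a signal per gene and library, which the authors describe as normalized expression from DESeq2. The values were not whole numbers, and the ratio of a library's values between 2 deposited tables differed from gene to gene, so read counts could not be recovered and the depth of the libraries is unknown. The authors deposited 4 such tables, 1 for each incision comparison and 1 for age in naive pups, each normalized on its own, and every comparison here stayed within 1 table unless stated. The same tables hold the authors' log2 fold changes with standard errors and the authors' p-values, raw and adjusted. Per the file headers and the deposited description, the authors kept genes with at least 10 counts in at least 4 samples before DESeq2 ran. They modelled sex and treatment at each age, tested age in naive pups with a likelihood ratio test over sex, and afterwards kept genes with normalized expression over 20 in a group and a coefficient of variation under 0.65 in a group. The genes available here are therefore those that passed filters on level and on spread within groups. The chance shares given below for genes whose groups do not overlap, and the splits of the libraries, take no account of these filters. The authors also deposited gene ontology terms from gProfiler with adjusted p-values under 0.01, for the genes they called at P4 and for 4 clusters of age-dependent genes with an adjusted p under 0.001, and the other values of those tables are counts of genes in each term.

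Groups came from the sample titles. The labels of 24 libraries held 2 conflicts of group and 4 conflicts of sex. The title of the library MB12 gives P10 incision, female 1, while its characteristics and the deposited sample sheet give a P10 naive pup. The title of MB16 gives P24 naive, female 1, while its characteristics and the sheet give a P10 incised pup. The sex in the title and in the sheet differs for MB12, MB14, MB16 and MB19. With the titles, 3 naive and 4 incised libraries formed the P10 comparison, MB12 did not enter the age comparison, and MB16 entered no comparison. Results with the sheet's groups are given beside the P10 results.

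For each gene, limma 3.58.1 in R 4.3.3, with the intensity trend and robust settings (statmod 1.5.0), was fitted to log2(value + 1) with group and sex as terms. Genes with a mean of at least 10 over the fitted libraries were tested, which left out 0 genes of the incision tables and 3 of the age table. Fold changes are on this log2 scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. The age table was tested for P10 against P4, P24 against P10, P24 against P4 and any difference between ages. Whether the incision effect differed between ages was tested in 1 model over the 3 incision tables, with sex as a term. Its differences between ages are not exactly the differences of the effects from the separate fits. This test sets levels from separately normalized tables side by side, although each effect was formed within its own table.

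Before the data were examined, 49 gene lists were fixed, and 45 had at least 3 tested members. They covered astrocyte identity and maturation, immature progenitors, the cell cycle, glutamate and GABA handling, ion, water and gap junction genes, receptors for purines and monoamines, synapse regulation, extracellular matrix, axon guidance, dorsoventral patterning, pan-reactive, A1 and A2 reactive genes, STAT3 signalling, cytokine and NF-kB genes, interferon, immediate early genes, glucocorticoid targets, circadian clock, heat shock, unfolded protein response, hypoxia, chromatin, BMP and TGF-beta, FGF, Notch, Wnt and Hedgehog signalling, glycolysis, oxidative phosphorylation, lipid handling, cholesterol synthesis, ribosomal proteins, nuclear long noncoding RNA, and markers of oligodendrocytes, their precursors, neurons, dorsal horn neurons, microglia, endothelial, mural, ependymal and Schwann cells and fibroblasts. Lists for blood cells, mitochondrial RNA, sex-linked genes and the sort reporter had too few tested members. Each list was tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, with adjustment over the 45 lists of a comparison. Members were also counted with p-values adjusted over the list alone. Exact permutation p-values of list means, given beside some called lists, were not adjusted. They rest on the same libraries as the calls and are not independent support.

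The rule for named genes, also set before the data were examined, took the 10 rising and 10 falling called genes with the largest change whose groups do not overlap and whose mean is at or above the median. Where fewer than 5 passed in a direction, it took the 5 genes with the smallest p. It added up to 4 members per list, those past the threshold first, and always Gfap, Aqp4, Slc1a2, Slc1a3, Aldh1l1, Sox9, Kcnj10 and Gja1. Some genes that this rule took are not reported here. Other genes are named as members of a list, as genes of the authors' tables or because a test of the difference between ages called them. Gene positions came from the GENCODE annotation of GRCm38, the build also known as mm10, and 98.1% of the genes in the P4 table had a length there. The kits and the counting leave open whether strand was used, so reads of overlapping antisense genes and of near-identical copies, such as pseudogenes of ribosomal protein genes and of Fth1, cannot be told apart here.

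The alternatives were the groups of the characteristics, both conflicting libraries left out, no sex term, the replicate number as a block, pseudocounts of 0.5 and 5, no filter on low values and a mean of at least 50, median-ratio rescaling and quantile normalization, limma without trend and robust settings, array quality weights, Spearman correlation, and each library left out in turn. Chosen after seeing the data were the sheet's groups and sex, the sheet's sex alone, the list tests with a library left out, with a block or with rescaled values, removal of a trend with gene span, and the P24 against P4 comparison without P10 libraries. The pipeline was tested on simulated data with the real means and spreads and 200 changed genes per comparison. With a log2 change of 2, the share of changed genes called was 59.8% for incision at P4, 50% at P10 and 94% at P24, and 77.6%, 77% and 81% for P10 against P4, P24 against P10 and P24 against P4. With a log2 change of 1, these shares were 10.1%, 4%, 64%, 30.3%, 26% and 41%. For the difference of incision effects between ages, 24 of 117 genes called in the simulation were unchanged ones, so this test called more false genes than its threshold names. In each of the 6 comparisons, 2 of 2 simulated lists shifted by 0.5 were called at the preset correlation, and at most 1 of 36 lists without shifted genes. The simulated genes varied independently, so this does not measure false list calls where genes vary together. With an estimated correlation, 1 of the 2 shifted lists was called at P4, 0 at P10 and 2 at P24. For P10 against P4, P24 against P10 and P24 against P4 these numbers were 1, 1 and 2. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for annotation and plots.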

Results

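The deposited tables held normalized nuclear RNA levels of sorted dorsal horn astrocyte nuclei from 24 mouse pups. By their titles these were 4 naive and 4 incised pups at P4, 3 naive and 4 incised at P10, and 5 naive and 4 incised at P24, of which 1 P24 naive library, MB16, entered no comparison. The study asked which genes change in these nuclei after a hindpaw incision on P3 and which change as naive pups grow. Column sums of the normalized values in the incision tables ran from 3880251 (MB4, P4) to 6512585 (MB17, P24). They are sums of normalized values, not sequencing depth, which is unknown. Spearman correlations between libraries of a group were 0.824 to 0.960 at P4, 0.880 to 0.928 at P10 and 0.957 to 0.977 at P24, so the P24 libraries resembled each other most.

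At P4, 1 day after incision, 4 genes were higher in incised pups (n = 4) than in naive pups (n = 4). Thbs1, which encodes the secreted matrix protein thrombospondin 1, rose from 87.7 ± 22.7 (SD) to 457 ± 130 normalized counts, a log2 change of 2.41 (SE 0.30, adjusted p = 0.0300). The tropomyosin gene Tpm2 rose from 49.95 ± 17.3 to 381 ± 158, a log2 change of 2.89 (SE 0.40, adjusted p = 0.0387). Fth1, the heavy chain of the iron store ferritin, rose from 965 ± 186 to 2374 ± 556 (log2 change 1.38, SE 0.20, adjusted p = 0.0387). Efemp1, which encodes the extracellular matrix glycoprotein fibulin 3, rose from 40.8 ± 14.2 to 208 ± 28.5 (log2 change 2.42, SE 0.35, adjusted p = 0.0387). On GRCm38 these protein-coding genes lie at chromosome 2, 118111876 to 118127133 on the plus strand (Thbs1), and chromosome 4, 43514711 to 43523765 on the minus strand (Tpm2). The others lie at chromosome 19, 9980598 to 9985098 on the plus strand (Fth1) and chromosome 11, 28853204 to 28926743 on the plus strand (Efemp1). All 4 libraries of the incised group were above all 4 of the naive group for each gene. Lgals1, which encodes galectin 1, did not pass (log2 change 2.16, adjusted p = 0.0661). No gene passed as lower. The lowest p-values in that direction belonged to Dync2h1, a dynein of cilia (log2 change -1.37, adjusted p = 0.0690), and Fgf14, an intracellular partner of sodium channels (-1.77, 0.0714). They were followed by the formin Daam1 (-1.54, 0.108), the leukaemia inhibitory factor receptor gene Lifr (-0.95, 0.182) and Eif4enif1 (-1.21, 0.182). Of 14243 genes tested with limma, 1141 had an unadjusted p under 0.05, 542 of them higher. The groups did not overlap for 5.90% of genes, against 2.86% by chance.

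**Figure D1:**
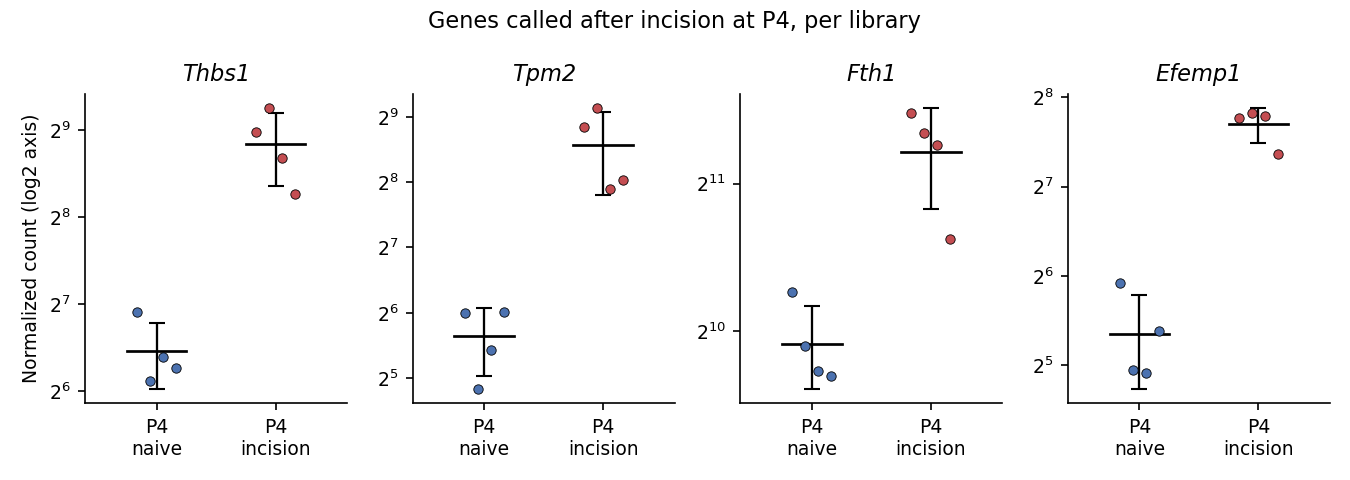
Normalized counts (vertical axis, log2 scale) of Thbs1, Tpm2, Fth1 and Efemp1 in 4 naive and 4 incised pups at P4, each point 1 library, with the group mean and SD in black. For each gene the incised libraries all lie above the naive ones.

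The astrocyte genes that were always examined did not pass at P4. Gfap, the intermediate filament of astrocytes, was at 12101 ± 2871 in naive and 8891 ± 1000 in incised pups (log2 change -0.47, adjusted p = 0.552). The water channel gene Aqp4 had a log2 change of 0.25, the glutamate transporter genes Slc1a2 and Slc1a3 of -0.05 and -0.16 and the folate enzyme gene Aldh1l1 of -0.00. The log2 change was -0.14 for the transcription factor gene Sox9, 0.45 for the potassium channel gene Kcnj10 and -0.19 for the connexin gene Gja1. Whether these 4 genes passed depended on individual libraries, while the log2 changes stayed at 2.25 to 2.55 for Thbs1, 2.61 to 3.13 for Tpm2 and 2.28 to 2.57 for Efemp1 with any 1 library left out. The count of called genes was 0 without naive M1, naive M2, incised F1, incised M1 or incised M2, 1 without naive F2, 7 without naive F1 and 8 without incised M3. The adjusted p of the 4 genes reached 0.136 without naive F2, 0.350 without naive M1, 0.2199 without naive M2, 0.702 without incised F1, 0.0948 without incised M1 and 0.0856 without incised M2. Without trend and robust settings 0 genes passed at P4 (adjusted p of the 4 genes 0.153 to 0.332), after removal of a trend with gene span Fth1 did not pass (adjusted p = 0.0716), and under quantile normalization 13 genes passed as higher and 2 as lower.

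The authors' deposited table called 76 genes at P4, 49 higher and 27 lower. All 76 had the same direction and an unadjusted p under 0.05 in limma, where their adjusted p-values ran from 0.0300 to 0.454. These genes were chosen on the same libraries, so this overlap is not independent evidence. The 49 higher genes, with a median log2 change of 1.66 here, included smooth muscle and cytoskeletal genes such as Acta2 (log2 change 2.67) and Tagln (1.90), the keratin gene Krt18 (2.66) and the annexin gene Anxa2 (1.37), of which none passed here. In the authors' deposited table of gene ontology terms, made for the higher and lower genes together, supramolecular fiber organization held 16 of 70 genes (the authors' adjusted p 2.57e-07) and cell migration 20 (2.57e-06). The mean log2 level of the higher set was 6.37 ± 0.25 in naive and 8.06 ± 0.24 in incised P4 libraries. In the P10 table it was 7.59 ± 0.29 in naive (n = 3) and 7.60 ± 0.26 in incised libraries (n = 4). In the age table it was 6.69 ± 0.25 in P4, 7.82 ± 0.30 in P10 and 6.68 ± 0.12 in P24 naive libraries, so naive P10 libraries also stood high for these genes.

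**Figure D2:**
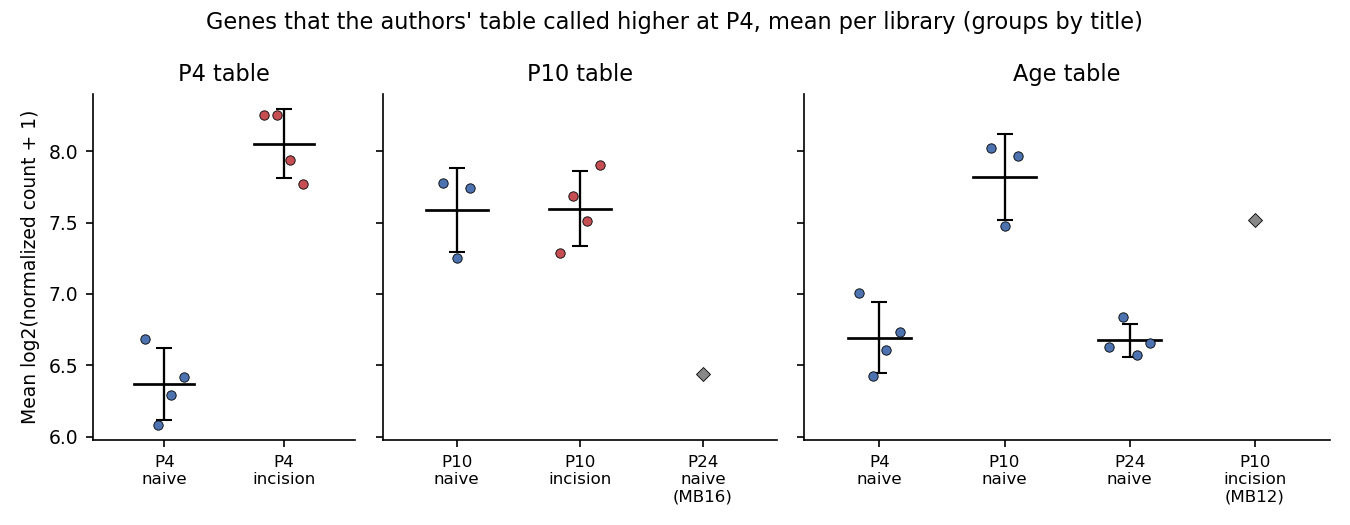
Mean log2(normalized count + 1) per library (vertical axis) of the genes that the authors' table called higher at P4, in the P4, P10 and age tables, with groups by title, each point 1 library and black bars the group mean and SD. The P10 naive libraries, at 7.82 ± 0.30 in the age table, lie above the P4 and P24 naive libraries, and grey diamonds mark MB16 and MB12, whose labels conflict.

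In all, 3 fixed lists were called higher at P4 by camera, and 0 of them with an estimated correlation. Ribosomal protein genes had a median log2 change of 0.49 with 21 of 21 members positive (adjusted p = 1.87e-09, and adjusted p = 0.641 with an estimated correlation). No member passed over all genes, while 9 of 21 were higher adjusted over the list alone, led by Rps19 (log2 change 0.93) and Rpl8 (0.79), both also in the authors' set of higher genes. The mean of the list was 8.83 ± 0.11 in naive and 9.25 ± 0.24 in incised libraries (2-sided exact permutation p = 0.0286, unadjusted and the smallest that 4 against 4 allow). Genes of cholesterol synthesis had a median of 0.31 (adjusted p = 0.0171, and adjusted p = 0.827 with an estimated correlation), with 20 of 24 members positive and 0 called either over all genes or adjusted over the list alone. Without naive M2 their median was 0.02 and their adjusted p 0.919, and the call was also lost without incised M3. Markers of mural cells, the smooth muscle cells and pericytes of vessels, had a median of 0.33 (adjusted p = 0.0461, and adjusted p = 0.641 with an estimated correlation). Their list mean was 5.78 ± 0.31 in naive and 6.53 ± 0.23 in incised libraries (exact permutation p = 0.0286), none of 7 members passed over all genes, and 2, the contractile genes Acta2 and Tagln, were higher adjusted over the list alone. That call was lost without naive F2, naive M1, incised F1, incised M2 or incised M3, with an adjusted p of up to 0.213. The number of lists called was 7 without naive M1, 5 without incised M2 and 1 without incised M3. The synapse regulation list, which holds Thbs1 and its relative Thbs2 (log2 change 0.07), was not called. The pan-reactive list was not called either, with Vim at 1.15 (adjusted p = 0.146) and Serpina3n at -0.17 (adjusted p = 0.868).

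At P10, 7 days after incision, no gene passed between 4 incised and 3 naive pups. Marker lists of neurons and oligodendrocytes were called higher in incised pups by camera, both by the titles and by the sheet. By the titles no list passed with an estimated correlation (adjusted p = 0.920 to 0.985 with an estimated correlation). With MB12 and MB16 both left out, the oligodendrocyte call was lost (median 0.23, camera adjusted p = 0.263). The calls of dorsal horn neurons and of neurons then held (camera adjusted p = 0.0365 for each). The lowest p-value among higher genes belonged to Cacna2d1, a calcium channel subunit bound by gabapentin, at 30.4 ± 5.47 in naive and 198 ± 91.8 in incised libraries (log2 change 2.47, SE 0.46, adjusted p = 0.126). Next came Kndc1, a guanine nucleotide exchange factor (2.37, SE 0.46, 0.148), Dock9, an activator of the GTPase Cdc42 (1.91, 0.432), the phosphatase gene Ptpn13 (2.86, 0.432) and the kinase-like gene Camkv (1.47, 0.449). Among lower genes it belonged to Gfap, at 25152 ± 2701 in naive and 16870 ± 2885 in incised libraries (log2 change -0.59, SE 0.14, adjusted p = 0.485). Behind it came Plekhh2 (-2.71, 0.499), Tmem87a (-1.89, 0.520), the apelin receptor gene Aplnr (-0.94, 0.520) and the interferon-induced gene Ifitm3 (-1.28, 0.520). Of the other astrocyte genes always examined, Aqp4 had a log2 change of 0.04, Slc1a2 of 0.03, Slc1a3 of 0.13, Aldh1l1 of -0.15, Sox9 of -0.19, Kcnj10 of 0.25 and Gja1 of 0.03. With limma, 0 of 13699 genes passed and 674 had an unadjusted p under 0.05. The groups did not overlap for 5.71% of genes, against 5.71% by chance. The count rose to 3 without naive F2 and to 2 without incised F2. The authors' deposited table called 2 genes at P10, Kndc1 (the authors' adjusted p 0.00281) and the potassium channel gene Kcnk2 (0.00575), both higher. That table holds 8 libraries, MB16 among them, which the deposited sample sheet gives as incised and with MB12 as naive, so its groups differ from those by title.

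With the groups and sexes of the deposited sample sheet, limma also called 0 genes at P10. Cacna2d1 then had a log2 change of 1.92, Kndc1 of 2.33, Gfap of -0.34 and Plekhh2 of -0.40. Markers of dorsal horn neurons had a median log2 change of 1.04 at P10 by the titles (adjusted p = 0.000928, and adjusted p = 0.920 with an estimated correlation) and 0.71 by the sheet (adjusted p = 0.00491). None of their 11 members passed over all genes, and 4 were higher adjusted over the list alone, the neuropeptide genes Grp (3.26), Sst (1.14) and Penk (1.04) and the dynorphin gene Pdyn (1.84). Markers of neurons had a median of 0.34 (adjusted p = 0.0123, and adjusted p = 0.985 with an estimated correlation; by the sheet 0.27, 0.0146). Of their 15 members 14 were positive, and 0 passed over all genes or adjusted over the list alone. These lists stood low in P10 naive libraries, at list means of 5.89 ± 0.10 against 6.83 ± 0.37 in incised libraries for dorsal horn neurons (exact permutation p = 0.0571) and 7.51 ± 0.27 against 7.98 ± 0.14 for neurons (exact permutation p = 0.0286). Oligodendrocyte markers had a median of 0.53 (adjusted p = 0.0123, and adjusted p = 0.985 with an estimated correlation; by the sheet 0.47, 0.0142), with 1 of 15 higher adjusted over the list alone, the myelin gene Opalin (2.64). Markers of oligodendrocyte precursors had a median of 0.46 (adjusted p = 0.0314, and adjusted p = 0.920 with an estimated correlation), with 1 of 9 higher adjusted over the list alone, the receptor gene Gpr17 (1.62). Wnt signalling genes had a median of 0.38 (adjusted p = 0.0314, and adjusted p = 0.985 with an estimated correlation), with 0 of 18 members called either way. Neither passed by the sheet (adjusted p = 0.202 and 0.192), where the cell cycle list was called with a median of 0.38 (adjusted p = 0.00491). By the sheet, the P10 lists were tested at the preset correlation alone, so whether these calls hold with an estimated one is unknown. The call of the dorsal horn neuron list held without any 1 library, with an adjusted p of up to 0.0365. The neuron call was lost without naive F2, incised F2 or incised M1 (adjusted p up to 0.306) and the oligodendrocyte call without naive F2, incised F1 or incised M1 (0.360), where the oligodendrocyte median was 0.27, 0.23 and 0.28. It reached 0.81 without incised F2. The Wnt call was lost without naive F1, naive M1, incised F2, incised M1 or incised M2 (0.461), and the precursor call whenever any 1 of the 7 libraries was left out (0.190), with a Wnt median as low as 0.19. The number of lists called was 3 without naive F1, naive F2, incised F1 or incised M2, 2 without incised F2 and 1 without incised M1.

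At P24, 21 days after incision, no gene passed between 4 incised and 4 naive pups, while the mean levels of oligodendrocyte markers and of precursor markers were lower in every incised library than in every naive one. Among higher genes, the lowest p-value belonged to Klhdc7b, at 64.0 ± 16.5 in naive and 140.0 ± 9.98 in incised libraries (log2 change 1.16, SE 0.24, adjusted p = 0.0898). Next were the sialomucin gene Podxl2 (0.95, 0.0898), the neprilysin gene Mme (1.64, 0.205), the phosphatase gene Ptp4a1 (0.69, 0.205) and the small GTPase gene Rab43 (0.97, 0.211). Among lower genes it belonged to the peroxidase gene Lpo, at 367 ± 65.1 in naive and 200 ± 35.8 in incised libraries (log2 change -0.87, SE 0.17, adjusted p = 0.0898). Next were the microtubule-associated gene Eml1 (-0.67, 0.0898), the matrilin gene Matn4 (-0.79, 0.0898), Clip3 (-0.59, 0.205) and Olig1, a transcription factor of the oligodendrocyte lineage (-0.59, 0.205). Among astrocyte genes always examined, Slc1a2 had a log2 change of -0.31, Kcnj10 of -0.29, Sox9 of 0.17, Aldh1l1 of -0.16, Aqp4 of -0.14, Gfap of 0.05, Gja1 of -0.05 and Slc1a3 of -0.01. With limma, 0 of 15246 genes passed and 1525 had an unadjusted p under 0.05. The groups did not overlap for 4.96% of genes, against 2.86% by chance. The count was 5 without naive F3, 2 without naive M1 or incised F1, and 1 without naive M2 or incised M1. The authors' deposited table called 8 genes, with Klhdc7b, the diacylglycerol kinase gene Dgke and the homeobox gene Hoxd8 higher and the myelin genes Mbp and Mobp, Eml1, Lpo and Samt1d lower.

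Oligodendrocyte markers had a median log2 change of -0.38 at P24 with 15 of 15 members negative (adjusted p = 3.26e-08, and adjusted p = 0.466 with an estimated correlation). None passed over all genes, and 12 were lower adjusted over the list alone, including Mbp, at 19248 ± 2109 in naive and 13881 ± 602 in incised libraries (log2 change -0.47), Mobp (-0.53), the myelin lipid enzyme gene Ugt8a (-0.49) and the tight junction gene Cldn11 (-0.46). The list mean was 11.37 ± 0.07 in naive libraries and lay between 10.84 and 11.09 in incised ones (2-sided exact permutation p = 0.0286, unadjusted and the smallest possible). Markers of oligodendrocyte precursors had a median of -0.42 with 9 of 9 members negative (adjusted p = 0.000126, and adjusted p = 0.466 with an estimated correlation). Of these, 5 were lower adjusted over the list alone, Olig1 (-0.59), the proteoglycan gene Cspg4 (-0.51), the growth factor receptor gene Pdgfra (-0.47), Gpr17 (-0.42) and Lhfpl3 (-0.42). Their list mean was 8.90 ± 0.14 in naive and 8.51 ± 0.10 in incised libraries (exact permutation p = 0.0286). Both calls held without any 1 library. Glycolysis genes, with a median of -0.20 (adjusted p = 0.00338, and adjusted p = 0.466 with an estimated correlation), also held without any 1 library, with 0 of 19 members called over all genes or adjusted over the list alone.

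**Figure D3:**
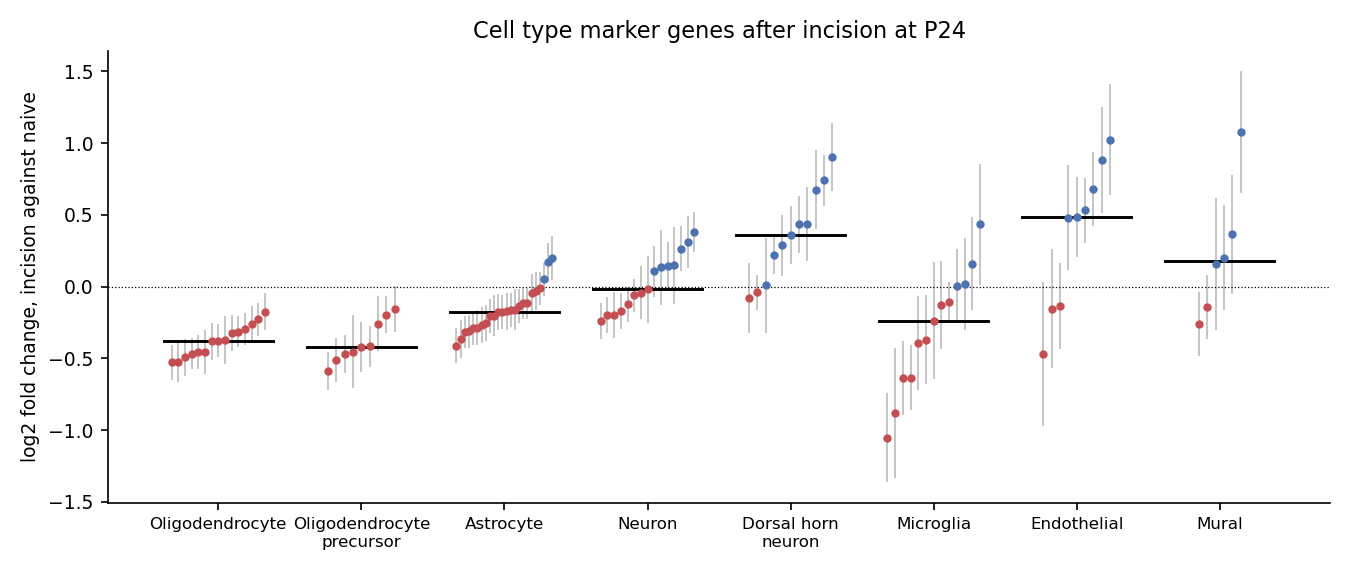
Log2 fold changes of incision against naive at P24 (vertical axis) for marker genes of 8 cell types, each point 1 gene with its SE, red below and blue above 0, and a black line at the list median. Oligodendrocyte and precursor markers have medians of -0.38 and -0.42, and dorsal horn neuron and endothelial markers of 0.36 and 0.48.

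Further lists called lower at P24 were astrocyte identity, with a median of -0.17 (adjusted p = 0.00669), astrocyte maturation at -0.18 (0.00919) and glutamate and GABA handling at -0.14 (0.0103). The same held for ribosomal proteins at -0.14 (0.0170), lipid handling at -0.18 (0.0194), oxidative phosphorylation at -0.15 (0.0238), cholesterol synthesis at -0.15 (0.0273) and FGF signalling at -0.21 (0.0435). Markers of dorsal horn neurons, with a median of 0.36 (adjusted p = 0.00338), and of endothelial cells, with a median of 0.48 (adjusted p = 0.0170), were called higher. Adjusted over the list alone, 2 dorsal horn neuron genes, Grp (0.90) and the neurotensin gene Nts (0.74), were higher, and 2 astrocyte maturation genes, 2 FGF genes and 1 glutamate and GABA gene were lower. Of these lists, 0 members passed over all genes. With an estimated correlation, 0 of the 13 lists called at P24 passed, with adjusted p = 0.466 to 0.658 with an estimated correlation. Quantile normalization ended 10 of the 13 calls and kept those of oligodendrocytes, precursors and dorsal horn neurons. Leaving out incised F2 ended 7 of the 13 calls, incised M2 6, naive F2 5, naive M1 4, naive M2 3, incised M1 2 and incised F1 1. The highest adjusted p of a lost call ran from 0.0701 (dorsal horn neurons) to 0.209 (FGF).

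Whether the incision effect differed between ages was tested in 1 model. Of 13200 genes, 12 passed and 1255 had an unadjusted p under 0.05. Pairwise, 29 genes differed between P10 and P4, 8 between P24 and P4 and 1 between P24 and P10. The effects per age given here came from the separate fit at each age, so they do not subtract exactly to the differences of this model. The genes called at P4 were prominent. The incision effect on Thbs1 was 2.41 at P4, -0.36 at P10 and -0.28 at P24 (P24 minus P4 -2.62, adjusted p = 0.0168). On Tpm2 it was 2.89, -0.05 and 0.17 (P10 minus P4 -2.92, adjusted p = 0.0137), and on Fth1 1.38, -0.15 and -0.28 (P24 minus P4 -1.58, adjusted p = 0.0168). Lgals1 (2.16 at P4, -0.06 at P10 and -0.06 at P24), the GABA transporter gene Slc6a11 (0.83, -0.10 and -0.41), BC005537 (1.56, -0.13 and -0.23) and Gatd3a (1.15, -0.22 and -0.28) also had larger effects at P4 than at P24 (adjusted p for P24 minus P4 from 0.0168 to 0.0406). For Slc6a11, P10 minus P4 did not pass (adjusted p = 0.0623). Fgf14 (-1.77 at P4, 0.84 at P10) and Wdr41 (-1.90 and 0.55) had lower effects at P4 than at P10 (adjusted p = 0.0137 and 0.0212). Kndc1 (2.37 at P10, -0.42 at P24, adjusted p = 0.00450), Dock9 (1.91 at P10, -0.35 at P4, adjusted p = 0.0256) and the Rap exchange factor gene Rapgef5 (3.82 at P10, -0.37 at P4, adjusted p = 0.0439) had effects that were higher at P10. This model used the titles. With the groups of the characteristics 1 gene passed, and with the groups and sexes of the sheet 22. The count was 20 without P4 naive F1, 6 without P4 naive F2 or P4 naive M2, 29, 56 and 25 without P4 incised M1, M2 and M3, 30 without P10 naive F2 and 19 without P10 incised M2.

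**Figure D4:**
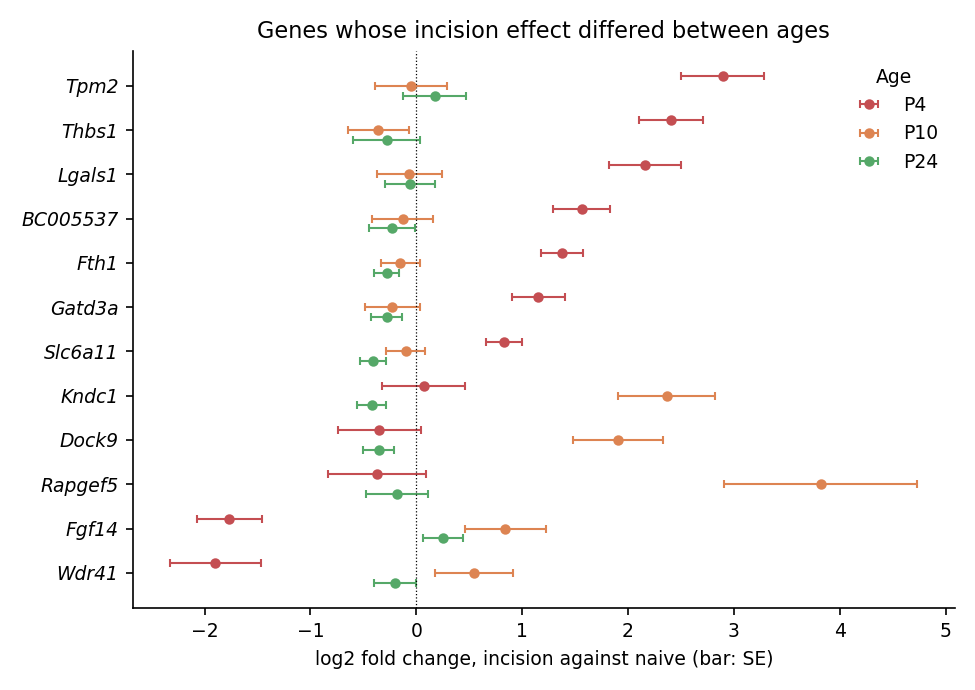
Log2 fold change of incision against naive (horizontal axis) at P4, P10 and P24 for the 12 genes whose effect differed between ages, with bars for the SE. Thbs1 and Tpm2 lie at 2.41 and 2.89 at P4 and near 0 at the later ages.

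The incision effects were also compared across genes with the change of naive pups between the other 2 ages. The groups compared share no libraries, but the age fit drew its sex term, spread and normalization from naive libraries of all ages. Across 14056 genes the effect at P4 had a Pearson r of -0.10 (Spearman rho -0.06) with the naive change from P10 to P24 (exact permutation p = 0.143, adjusted p = 0.214, from 35 splits of the libraries). At P10 the values were 0.05 and 0.03 with the change from P4 to P24 (exact p = 0.571, adjusted p = 0.571), and at P24 -0.18 and -0.19 with the change from P4 to P10 (exact p = 0.0286, adjusted p = 0.0857). None passed after adjustment over the 3 relations, and genes are not independent replicates.

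Far more genes differed between ages in naive pups than between incised and naive pups. Marker lists of other cell types were among those that changed, so changes within astrocytes and changes in the nuclei sorted cannot be told apart here. The labels give no batch, so age cannot be separated from how each age group was prepared. From P4 (n = 4) to P10 (n = 3), camera called oligodendrocyte markers higher and cell cycle genes lower, and neither list passed with an estimated correlation (adjusted p = 0.166 and 0.310 with an estimated correlation). Mbp, which encodes myelin basic protein, rose from 564 ± 290 to 9433 ± 2230 normalized counts (log2 change 4.35, SE 0.50, adjusted p = 0.00112), and the log2 change of Mobp was 3.86. Other genes with the largest rises were Myoc, which encodes the secreted protein myocilin (4.97), Hsd11b1, the enzyme that regenerates active glucocorticoid (3.33), Igsf1 (3.26), the glycogen phosphorylase gene Pygm (3.17), the small heat shock gene Cryab (3.05), Cldn11 (2.99), Thrsp (2.97) and Aplnr (2.81). The imprinted noncoding RNA Meg3 fell from 18756 ± 3629 to 1830 ± 219 (log2 change -3.32, SE 0.17, adjusted p = 1.27e-10). Its neighbour Rian had a log2 change of -2.72 and the imprint-keeping zinc finger gene Zfp57 of -3.54. Other large falls were those of the Wnt antagonist gene Frzb (-3.29), Cd1d1 (-3.24), the channel subunit genes Cacna2d1 (-2.95) and Scn3b (-2.92), the spindle gene Tpx2 (-2.83) and Syt4 (-2.78). Astrocyte genes moved apart. Gfap (1.05), Aqp4 (0.83), Slc1a2 (1.51) and Kcnj10 (1.23) rose and Slc1a3 (-1.27) fell, while Aldh1l1 (0.06), Sox9 (0.31) and Gja1 (-0.12) did not pass. In all, limma called 2050 of 14982 genes, 1071 higher and 979 lower, and 4143 had an unadjusted p under 0.05. The groups did not overlap for 19.6% of genes, against 5.71% by chance.

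Of 45 lists, 12 were called higher and 6 lower from P4 to P10, and 0 passed with an estimated correlation. Of 15 oligodendrocyte markers 13 rose (median 1.67, adjusted p = 5.63e-12, and adjusted p = 0.166 with an estimated correlation), the same count adjusted over the list alone. Of 26 cell cycle genes 17 fell, 20 adjusted over the list alone (median -1.77, adjusted p = 1.03e-11, and adjusted p = 0.310 with an estimated correlation), such as the anaphase gene Cdc20 (-4.52) and the replication gene Mcm2 (-3.12). Of 24 astrocyte identity genes 13 rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.74, adjusted p = 1.71e-07, and adjusted p = 0.343 with an estimated correlation), with rises of the tissue factor gene F3 (2.08), the neurotensin receptor gene Ntsr2 (2.00) and the connexin gene Gjb6 (1.64). Of 16 oxidative phosphorylation genes 12 rose, 14 adjusted over the list alone (median 0.63, adjusted p = 6.89e-07, and adjusted p = 0.349 with an estimated correlation). Of 19 glycolysis genes 10 rose, 11 with 2 lower adjusted over the list alone (median 0.49, adjusted p = 0.000205, and adjusted p = 0.310 with an estimated correlation). Of 17 circadian clock genes 9 rose, 13 with 1 lower adjusted over the list alone (median 0.89, adjusted p = 8.02e-06, and adjusted p = 0.166 with an estimated correlation), including Dbp (2.53) and Per3 (1.73). Of 11 dorsal horn neuron markers 6 fell, 7 adjusted over the list alone (median -0.96, adjusted p = 0.000219, and adjusted p = 0.166 with an estimated correlation), among them Grp (-4.17) and Pdyn (-2.66). Of 18 astrocyte maturation genes 8 rose and 1, the glutamate receptor gene Grm3 (-1.66), fell, 9 and 2 adjusted over the list alone (median 0.69, adjusted p = 0.000468, and adjusted p = 0.398 with an estimated correlation), led by the clusterin gene Clu (2.17).

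The remaining calls from P4 to P10 were smaller. Higher were receptors for purines and monoamines (median 0.31, adjusted p = 0.00283, 5 of 19 higher and 1 lower), ribosomal proteins (0.34, 0.00359, 3 of 21 higher), and glucocorticoid targets (0.56, 0.00461, 5 of 17 higher). So were cholesterol synthesis (0.35, 0.0104, 4 of 24 higher), lipid handling (0.35, 0.0105, 6 of 20 higher and 2 lower) and ion, water and gap junction genes (0.40, 0.0230, 6 of 18 higher). Lower were axon guidance (median -0.54, adjusted p = 0.00455, 6 of 27 lower), immature progenitors (-0.46, 0.0132, 5 of 19 lower), Wnt signalling (-0.23, 0.0321, 4 of 19 lower) and neurons (-0.62, 0.0374, 6 of 15 lower and 1 higher). Adjusted over the list alone these counts were unchanged for the purine and monoamine receptors, ribosomal proteins, glucocorticoid targets, cholesterol synthesis and Wnt signalling. They became 9 higher and 2 lower for lipid handling, 9 higher for ion, water and gap junction genes, 9 lower for axon guidance, 6 lower for immature progenitors, and 8 lower and 3 higher for neurons. For these 10 lists adjusted p = 0.166 to 0.683 with an estimated correlation. Calls were lost without P10 naive F1 for cholesterol synthesis, lipid handling, ribosomal proteins and Wnt signalling, and without P10 naive M1 for ribosomal proteins and Wnt signalling. They were lost without P10 naive F2 for ion, water and gap junction genes and for neurons, without P4 naive M2 for cholesterol synthesis, Wnt signalling and neurons, and without P4 naive F2 for neurons. The adjusted p then reached 0.169 for cholesterol synthesis, 0.0803 for lipid handling, 0.0647 for ribosomal proteins, 0.141 for Wnt signalling, 0.115 for ion, water and gap junction genes and 0.128 for neurons. The P10 naive libraries of this comparison were also those in which the authors' P4 set stood high, at 7.82 ± 0.30, and 26 of 47 genes of that set rose from P4 to P10.

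From P10 (n = 3) to P24 (n = 4), the largest rises were those of Opalin and Hapln2, which mature oligodendrocytes express. Opalin rose from 9.86 ± 6.52 to 1075 ± 96.8 normalized counts (log2 change 6.91, SE 0.45, adjusted p = 9.35e-10), the perinodal matrix gene Hapln2 from 16.2 ± 12.8 to 1609 ± 390 (6.57, SE 0.36, adjusted p = 1.51e-10). The log2 change of the myelin gene Mog was 4.10 and that of the connexin gene Gjc3 4.08. Rises also included Etnppl, an enzyme of phospholipid breakdown found in astrocytes (6.26), the carbonic anhydrase gene Car14 (5.20), Evi2a (5.12), Kndc1 (4.29), Fam107a (4.27) and the potassium channel gene Kcna1 (4.05). Among falling genes were the phospholipase gene Pla2g3 (-3.21), Igfbp2 (-2.80), Inka2 (-2.78), Thbs1 (-2.69), Anxa2 (-2.62), the cyclin gene Ccnd2 (-2.36), the radial glial fatty acid binding gene Fabp7 (-2.36), Angptl4 (-2.30), Sncaip (-2.26) and the tenascin gene Tnc (-2.13). Gfap (-0.76), Aqp4 (-0.52), Slc1a3 (-0.75), Aldh1l1 (-0.79) and Sox9 (-0.80) fell and Gja1 (0.69) rose, while Slc1a2 (-0.23) and Kcnj10 (0.42) did not pass. Thbs1 and Anxa2 belong to the authors' P4 set, of which 28 of 47 genes fell and 3 rose at this step. Meg3 rose again, with a log2 change of 3.02, to 15373 ± 3142. In all, limma called 2140 of 14982 genes, 1327 higher and 813 lower, and 4026 had an unadjusted p under 0.05. The groups did not overlap for 22.5% of genes, against 5.71% by chance.

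From P10 to P24, 9 lists were called higher and 6 lower, and precursor markers alone passed with an estimated correlation. Of 15 oligodendrocyte markers 14 rose, also adjusted over the list alone (median 2.63, adjusted p = 9.41e-18, and adjusted p = 0.135 with an estimated correlation). Of 9 precursor markers 7 rose, also adjusted over the list alone (median 1.55, adjusted p = 7.00e-07, and adjusted p = 0.0416 with an estimated correlation), among them the sialidase gene Neu4 (3.42) and Gpr17 (3.11). Of 11 dorsal horn neuron markers 8 rose, 9 adjusted over the list alone (median 1.38, adjusted p = 6.65e-05, and adjusted p = 0.156 with an estimated correlation), such as Grp (3.12) and Penk (2.21). Of 15 neuron markers 6 rose, 11 with 1 lower adjusted over the list alone (median 0.77, adjusted p = 0.000941, and adjusted p = 0.412 with an estimated correlation), such as Snap25 (1.94). These lists had stood low in P10 naive libraries, with means of 7.42 ± 0.22 at P4 and 6.10 ± 0.12 at P10 for dorsal horn neurons and 8.24 ± 0.20 and 7.70 ± 0.28 for neurons. Of 12 microglia markers 4 rose, 6 adjusted over the list alone (median 0.95, adjusted p = 0.000605, and adjusted p = 0.262 with an estimated correlation). Of 19 immature progenitor genes 9 fell, 9 with 1 higher adjusted over the list alone (median -0.72, adjusted p = 0.000918, and adjusted p = 0.0884 with an estimated correlation), including Fabp7, Tnc, the Notch effector gene Hes5 (-2.08) and Vim (-1.36).

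**Figure D5:**
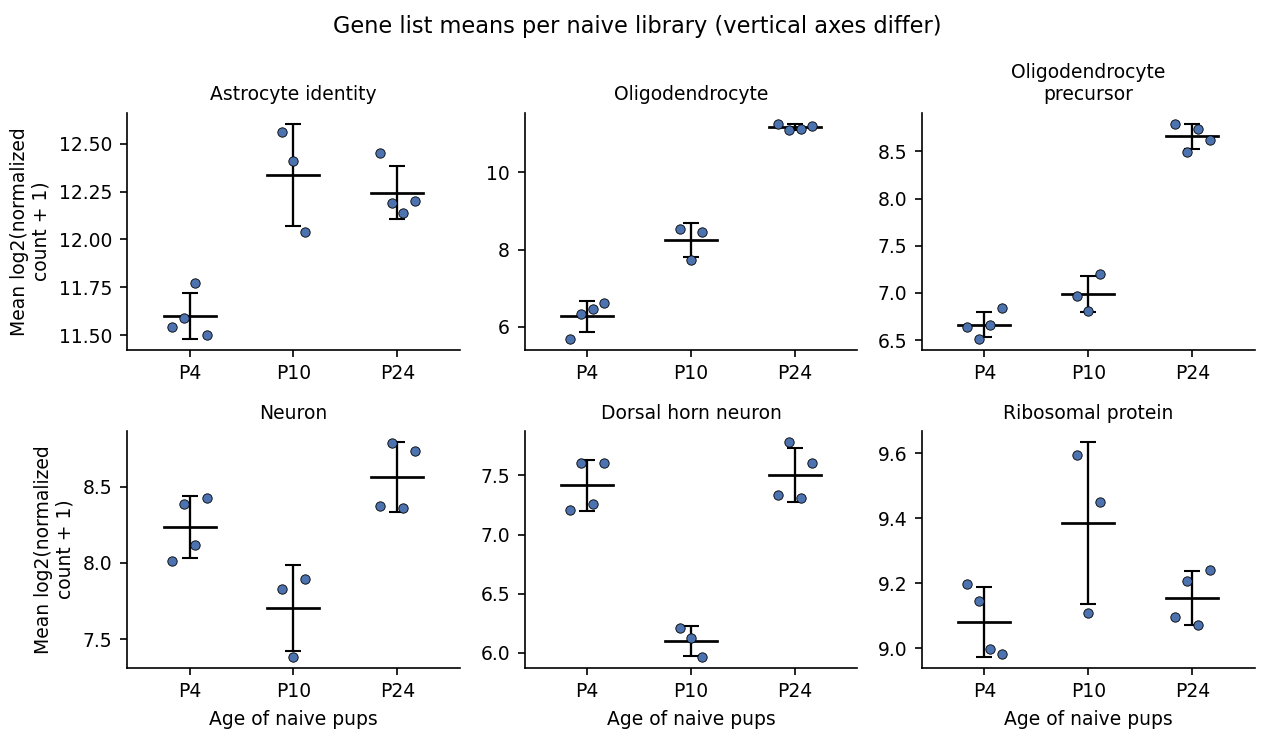
Mean log2(normalized count + 1) per naive library (vertical axes, which differ between panels) of 6 gene lists at P4 (n = 4), P10 (n = 3) and P24 (n = 4), each point 1 library with the group mean and SD in black. The dorsal horn neuron list falls from 7.42 ± 0.22 at P4 to 6.10 ± 0.12 at P10, and the oligodendrocyte list rises at both steps.

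The other lists called from P10 to P24 were glucocorticoid targets (median 0.64, adjusted p = 0.0263, 6 of 17 higher and 1 lower), with the kinase gene Sgk1 (3.38) and Cdkn1a (1.77), and ion, water and gap junction genes (0.57, 0.0263, 7 of 18 higher and 2 lower). A1 reactive genes (0.93, 0.0263, 4 of 13 higher) and nuclear long noncoding RNA (1.03, 0.0454, 3 of 4 higher and 1, Malat1 at -0.41, lower) were also called higher. Called lower were ribosomal proteins (-0.28, 0.0263, 2 of 21 lower), BMP and TGF-beta signalling (-0.48, 0.0294, 4 of 18 lower and 1 higher), Notch signalling (-0.44, 0.0306, 6 of 16 lower and 2 higher), and also dorsoventral patterning (-0.63, 0.0423, 5 of 14 lower) and glutamate and GABA handling (-0.31, 0.0423, 8 of 21 lower and 2 higher). Adjusted over the list alone, the counts were 8 higher and 1 lower for glucocorticoid targets, 6 higher for A1 genes, 7 lower and 2 higher for BMP and TGF-beta, 5 lower and 1 higher for dorsoventral patterning and 9 lower and 4 higher for glutamate and GABA handling, and the same for the others. For the ribosomal list adjusted p = 0.6246 with an estimated correlation, and for the other 8 it lay between 0.262 and 0.499. Each of the 9 calls was lost without at least 1 library. The library whose absence ended most of them was P10 naive M1 with 7, then P10 naive F1 with 6, P10 naive F2 with 5, P24 naive F3 with 4 and P4 naive F1 with 3. The others were P24 naive F2, P24 naive M2 and P4 naive M2 with 2 and P24 naive M1 and P4 naive F2 with 1. The adjusted p of a lost call reached at most 0.203, for ribosomal proteins, and without P10 naive M1 the number of lists called at this step was 8.

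From P4 to P24 limma called 2913 genes, 1740 higher and 1173 lower, with 4594 at an unadjusted p under 0.05. The groups did not overlap for 26.7% of genes, against 2.86% by chance. All 15 oligodendrocyte markers rose, also adjusted over the list alone (median 5.34, adjusted p = 4.62e-25, and adjusted p = 0.0567 with an estimated correlation), with Mog rising from 16.9 ± 7.09 to 3491 ± 288 (log2 change 7.70, SE 0.26, adjusted p = 1.46e-14). Precursor markers rose in 7 of 9 cases, 8 adjusted over the list alone (median 1.93, adjusted p = 1.48e-08, and adjusted p = 0.0139 with an estimated correlation). Immature progenitor genes fell in 11 of 19 and rose in 1, also adjusted over the list alone (median -0.95, adjusted p = 5.18e-07, and adjusted p = 0.0139 with an estimated correlation), led by Tnc (-3.45), Fabp7 (-3.42) and Hes5 (-2.82). Glucocorticoid targets rose in 13 of 17 and fell in 1, also adjusted over the list alone (median 1.29, adjusted p = 5.18e-07, and adjusted p = 0.215 with an estimated correlation), with Sgk1 (4.14) and Tsc22d3 (2.67) as examples. Oxidative phosphorylation (median 0.78, adjusted p = 8.13e-08, 14 of 16 higher), glycolysis (0.90, 1.05e-06, 15 of 19 higher and 2 lower), ion, water and gap junction genes (0.44, 0.000171, 9 of 18 higher) and the circadian clock (0.83, 0.00129, 10 of 17 higher and 1 lower) were called higher. So were astrocyte identity (0.57, 0.00135, 12 of 24 higher and 5 lower), purine and monoamine receptors (0.55, 0.00827, 9 of 19 higher and 2 lower), astrocyte maturation (0.68, 0.0214, 10 of 18 higher and 3 lower), heat shock genes (0.38, 0.0218, 4 of 10 higher) and microglia markers (0.62, 0.0249, 2 of 12 higher). Cell cycle genes (median -1.51, adjusted p = 3.89e-09, 13 of 26 lower), Wnt signalling (-0.67, 0.000476, 8 of 19 lower), axon guidance (-0.67, 0.00325, 11 of 27 lower and 2 higher), Notch signalling (-0.49, 0.0123, 5 of 16 lower and 1 higher), dorsoventral patterning (-0.69, 0.0214, 6 of 14 lower and 1 higher) and BMP and TGF-beta signalling (-0.52, 0.0428, 7 of 18 lower and 3 higher) were called lower. For these 15 lists adjusted p = 0.128 to 0.528 with an estimated correlation. Adjusted over the list alone, 17 cell cycle, 10 Wnt and 13 axon guidance genes were lower, the last with 3 higher. The counts of higher and lower members became 15 and 0 for oxidative phosphorylation, 15 and 3 for glycolysis, 11 and 2 for the circadian clock, 10 and 2 for the receptors and 10 and 5 for astrocyte maturation. They became 5 and 0 for heat shock, 2 and 7 for Notch and 3 and 8 for BMP and TGF-beta, and stayed the same for the other 4 lists. Calls were lost for heat shock without P4 naive F2 or P24 naive F2 (adjusted p up to 0.0693), for microglia without P4 naive F1 (0.0693) and for BMP and TGF-beta when any 1 of 7 libraries was left out, P4 naive F1 and M1, the 3 P10 naive libraries and P24 naive M1 and M2 (0.0987).

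Over all ages, limma called 4034 of 14982 genes, with 5702 at an unadjusted p under 0.05. The authors' deposited table called 4288 with its likelihood ratio test, and 3645 were called by both. The authors' table includes MB12, a P10 naive pup by the sheet, which the fit by titles left out. With the groups and sexes of the sheet, 3719 genes passed over all ages, 1968 from P4 to P10, 1963 from P10 to P24 and 2714 from P4 to P24. Of the 4034 genes, 1075 (26.7%) rose at both steps by their group means, 670 (16.6%) fell at both, 1027 (25.5%) were highest and 1262 (31.3%) lowest at P10. With each step tested, 132 genes rose at both, 50 fell at both, 174 rose and then fell, and 372 fell and then rose. The authors' clusters were read from the genes listed under at least 1 term in the authors' deposited table of terms, and the medians are over those genes alone. Unlike the fits by titles, these medians used plain group means by the sheet, with MB12 as P10 naive and no sex term. In cluster 1 (919 such genes) the median log2 changes were 0.83 and then 0.52, and in the authors' deposited table of terms 76 of 906 took part in the generation of precursor metabolites and energy (the authors' adjusted p 1.03e-25). Cluster 2 had medians of -0.31 and -0.81, with neuron projection development holding 85 of 555 genes in the authors' deposited table (6.03e-22). Cluster 3 had -1.53 and 0.63, with the mitotic cell cycle holding 31 of 182 genes in the authors' deposited table (3.44e-11), and cluster 4 had -0.58 and 1.73, with synaptic signaling among its terms in the authors' deposited table (34 genes, 3.05e-09). The authors formed these clusters on the same libraries.

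Of the 45 tested lists 15 were called in no comparison. Their smallest adjusted p-values were 0.0720 for A2 reactive genes, 0.0880 for synapse regulation, 0.0948 for chromatin, 0.108 for cytokine and NF-kB genes, 0.109 for pan-reactive genes, 0.115 for extracellular matrix, 0.132 for hypoxia, 0.169 for STAT3 signalling, and 0.205 for Schwann cells. For the others they were 0.2495 for ependymal cells, 0.262 for immediate early genes, 0.299 for the unfolded protein response, 0.350 for interferon and for Hedgehog signalling and 0.352 for fibroblasts. Lists of reactive astrocyte genes were thus called at 1 step, A1 genes from P10 to P24 in naive pups, and in 0 of the 3 incision comparisons. The A1 call was lost with an estimated correlation.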

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

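The tests on the P4 gene set, on the oligodendrocyte genes at P24, on the labels and on the precursor list under the sheet's labels were chosen after seeing the result they test, whereas the splits of the libraries were planned before the data were examined.

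The genes higher at P4 after incision were also high in naive P10 libraries, which may reflect RNA from another source in some libraries. Across 48 genes of the authors' higher set, the change at P4 had a Pearson r of 0.644 with the level in P10 naive libraries above the other naive libraries, but both values contain the P4 naive libraries, and r was 0.214 over all 14057 genes. Measured against P24 naive libraries alone, r was 0.498, which 187 of 10000 random lists of matched level reached, so another source stays open, as does an effect of incision. Mural cells and more cytoplasmic RNA stay open too. Mural and fibroblast markers outside the set had a median of 0.341 (quartiles -0.03 and 0.45), with none called over all genes, but leave out Acta2 and Tagln of the set. All 21 ribosomal protein genes had positive log2 changes, with none called over all genes. Together with oxidative phosphorylation genes their median was 0.38 (0.340 outside the set, whose median was 1.66). After a trend with gene span was removed, the median of the lower set was -1.17 (-1.16 before). Over all genes that trend was weak (Spearman rho -0.11 of the P4 change with span), so its removal could hardly move these genes. The median span was 42.2 kb in the lower set and 9.1 kb in the higher set, against 24.85 kb for all genes tested at P4. A bias with gene length therefore stays open. Genes of the lower set were only slightly lower in P10 naive libraries (median -0.176), which gives little sign of a source of RNA shared with those libraries. Age differs there too, and a source particular to the P4 incised libraries was not tested, so another source stays open for them as well.

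Oligodendrocyte and precursor genes were lower after incision at P24, by medians of -0.38 and -0.42 (upper quartile -0.29 together). A smaller share of other cell types in the sort might lower them. The 20 endothelial and dorsal horn neuron markers had a median of 0.435, but both lists had already been called higher, so they are no independent test. The 69 markers of all other cell types had a median of 0.02 (lower quartile -0.17). They include those 20, so they are no independent test of a general loss of other cells either. Outside those 20, the median was 0.18 for mural, 0.30 for Schwann, -0.01 for ependymal and -0.09 for fibroblast markers, none of them called. Neuron markers stayed level (-0.02), while microglia markers were lower without passing (-0.24, adjusted p = 0.0531). A smaller share of oligodendrocyte lineage nuclei, with or without microglia, stays open beside a change of these genes by incision, since 0 of these lists passed with an estimated correlation.

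The labels of MB12 and MB16 give 2 groups each, and the title's age for MB16 could be wrong. Along the change from P10 to P24, with 0 at the other libraries of its table and 1 at P24, MB16 lay at 0.315, near MB14 at 0.283. Its oligodendrocyte mean of 9.27 was within the range of the other P10-table libraries (7.54 to 9.28). In naive libraries that mean rose by 2.92 from P10 to P24. The position and the oligodendrocyte mean speak against a P24 pup. For the authors' higher P4 set, MB16 had a low mean, 6.44 against 7.25 to 7.91 in the other P10-table libraries. Among naive libraries the mean of this set was as low at P4 (6.69 ± 0.25) as at P24 (6.68 ± 0.12), so a low value is not particular to P24. Of the 4 libraries with 2 sexes in the labels, 3 had an Eif2s3x value nearer the sex in the sheet. MB19, titled male, lay at 410 normalized counts, above every undisputed P24 male (highest 240.0), and MB12 and MB16, titled female, at 134 and 117, below every undisputed P10 female (185 to 315), all on the side of the sheet, while MB14, at 198, lay where P10 females and males (138 to 237) overlap. The sex of MB14, the age of MB16 and the group of MB12 stay open.

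Genes were marked where the incision effect differed between ages past the threshold, with P24 minus P4 at -1.80 for BC005537, -1.58 for Fth1, -1.40 for Gatd3a, -2.18 for Lgals1, -1.32 for Slc6a11 and -2.62 for Thbs1. P10 minus P4 was 2.29 for Dock9, 2.52 for Fgf14, 3.79 for Rapgef5, -2.92 for Tpm2 and 2.71 for Wdr41, and P24 minus P10 was -2.88 for Kndc1. The list of oligodendrocyte precursor markers differed between P10 and P24 by a median of -0.87 (adjusted p = 4.65e-05, and adjusted p = 0.0129 with an estimated correlation) by the titles, and by -0.61 (adjusted p = 0.000613, and adjusted p = 0.0949 with an estimated correlation) by the sheet.

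Single libraries were marked when Dixon's test at 0.05 set them apart from the rest of their group. This happened in 27 of 357 groups tested, and chance alone marks about 1 in 20. At P4, naive F1 had a Daam1 value of 541 normalized counts (others 954 to 1005), naive F2 a Thbs2 value of 135 (72.8 to 73.6) and a Wdr41 value of 140.1 (90.1 to 96.3). Incised M3 had an Efemp1 value of 165 (217 to 226) and a Sox9 value of 2498 (2187 to 2224), incised M2 a Kcnj10 value of 341 (518 to 534) and incised M1 a Thbs2 value of 175 (62.7 to 74.9). At P10, incised M2 had an Opalin value of 24.03 (50.2 to 52.1) and incised F2 an astrocyte identity mean of 12.22 (11.99 to 12). At P24, naive F3 had a Klhdc7b value of 39.4 (69.8 to 73.7), incised M2 a Pdgfra value of 563 (738 to 768) and incised F1 an Slc1a2 value of 7108 (4681 to 4954) and 11.9% of its sum in the 10 highest genes (10.3% to 10.5%). Naive F2 had an astrocyte identity mean of 12.66 (12.37 to 12.40). The column sum of P4 naive M2 in megacounts (3880251 in full for the P4 table) was 3.88 in the P4 table (4.23 to 4.29) and 4.61 in the age table (5.05 to 5.09).

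In the age table, P4 naive M2 had a Car14 value of 238 (44.8 to 74.7) and a Kcna1 value of 82.5 (52.4 to 57.3), P4 naive M1 a Cryab value of 79.5 (29.8 to 38.0) and P4 naive F1 a Cdkn1a value of 323 (228 to 241), a Penk value of 364 (588 to 597) and a Snap25 value of 758 (1219 to 1251). P24 naive F2 had an Aldh1l1 value of 1181 (860 to 899), a Gjb6 value of 9791 (8152 to 8410), a Pdyn value of 84.9 (135 to 138) and a Rian value of 246 (340 to 351), and P24 naive M1 a Pla2g3 value of 97.1 (69.4 to 73.8). The Efemp1 value of incised M3 still lay above every naive value.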

How the results depend on the processing

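The settings with the groups and sexes of the deposited sample sheet, the sheet's sex, the gene span trend and no P10 naive libraries were chosen after seeing the data, as were list tests without a library, with a replicate block or after rescaling. Of 490 results for named genes, 58 were lost and 6 gained with array quality weights, 94 lost without trend and robust settings, 64 lost and 7 gained with the replicate block in place of sex, 17 lost and 4 gained with quantile normalization and 18 lost and 3 gained without a sex term. Of 270 list results, 70 were lost with an estimated correlation, 27 lost and 19 gained with fry, 14 lost and 6 gained with the replicate block, and 11 lost and 4 gained with quantile normalization. The sheet's groups and sexes lost 36 gene and 8 list results, and the groups of the characteristics 32 and 5. Pseudocounts of 0.5 and 5 lost 4 and 2 gene results, median-ratio rescaling 1 and removal of the span trend 13, and dropping the filter changed no call of a named gene. Quantile normalization gave 1040 higher and 1093 lower genes from P4 to P10 (1071 and 979 as reported) and 1658 and 1646 from P4 to P24 (1740 and 1173). The cause was not tested.

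Genes called at P4 numbered 4 as reported, 12 without a sex term, 15 with quantile normalization, 9 with a mean of at least 50, 0 without trend and robust settings and 19 with array quality weights. Genes called at P10 numbered 4 with array quality weights. P10 against P4 gave 1347 genes without trend and robust settings and 1169 with array quality weights, and P24 against P4 gave 4435 with those weights. Genes whose incision effect differed between ages numbered 1 with the groups of the characteristics, 22 with the sheet's groups and sexes, 32 with quantile normalization, 6 without trend and robust settings and 19 with array quality weights. Lists called at P10 numbered 3 with both conflicting libraries left out, and lists called at P24 numbered 5 with quantile normalization. With an estimated correlation, 0 lists were called at P4, at P10, at P24 and for P10 against P4, 1 for P24 against P10 and 2 for P24 against P4, and with fry 1 at P4, 0 at P10 and 0 at P24.

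Equal replicate numbers gave no sign of pairing. The deviations of equally numbered libraries from their group means correlated at -0.124 to 0.026 in 9 pairs. With so few libraries per group, this does not exclude a pairing. With the replicate block in place of sex, 14 genes were called at P10, 16 at P24 and 1287 for P24 against P10, and 1 list was called at P4, 3 at P10 and 9 for P24 against P10.

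With each library left out in turn, genes called ranged over 0 to 8 at P4, 0 to 3 at P10 and 0 to 5 at P24, and those differing between ages over 6 to 56. Lists called ranged over 1 to 7 at P4, 1 to 4 at P10, 6 to 19 at P24 and 8 to 15 for P24 against P10. The cell cycle list at P4, not called as reported (median 0.24), ranged over -0.39 to 0.73, and it was called in the opposite direction (adjusted p = 0.0129) without naive M2.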

Other observations

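All splits of the libraries were planned before the data were examined, their restriction to both sexes on both sides was chosen after seeing the result, and the difference of list shifts between ages was read after the lists had been called.

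At P4 the ribosomal protein genes shifted up after incision and at P24 down, and the difference was called by camera (P24 minus P4 -0.54, adjusted p = 1.39e-12, and adjusted p = 0.246 with an estimated correlation), with the P10 shift also below that at P4 (-0.50, adjusted p = 2.94e-08, and adjusted p = 0.740 with an estimated correlation). Differences in the same direction were called for cholesterol synthesis (P24 minus P4 -0.50, adjusted p = 2.47e-05, and adjusted p = 0.377 with an estimated correlation), lipid handling (-0.45, 5.73e-05, 0.246) and astrocyte maturation (-0.40, 7.07e-05, 0.291). Markers of dorsal horn neurons moved the other way, with a shift at P10 above that at P4 by 1.34 (adjusted p = 0.00121, and adjusted p = 0.740 with an estimated correlation). For oligodendrocytes the P24 shift lay below the P10 shift by -0.83 (adjusted p = 0.00966, and adjusted p = 0.785 with an estimated correlation).

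The libraries of each incision comparison were regrouped in all 35 ways of splitting them, counting the real grouping. At P4, 4 of 35 splits called at least as many genes as the 4 called by treatment, and the highest other count was 196, for MB1, MB2 and MB5, the 3 females, together with MB8. The 3 other splits with as many calls each set the 3 females and 1 male against the other males, and beside the sex term such a split compares 1 male with 4. Among the 30 splits with both sexes on both sides, 1, the real grouping, called as many genes, and the highest other count was 0. At P10 and P24, where treatment called 0 genes, all 35 splits called at least as many, with 16 and 6 as the highest other counts. For gene lists, 20 of 35 splits called at least the 3 lists of P4 (highest other 10), 2 of 35 the 5 lists of P10 (highest other 6), and 1 of 35, the real grouping, the 13 lists of P24 (highest other 12). With both sexes on both sides these numbers were 17 of 30, 1 of 30 and 1 of 34.

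The correlation of the incision effect with development was as far from 0 in 5 of 35 splits at P4 (real -0.10, highest other 0.128), 20 of 35 at P10 (0.05, highest other 0.170) and 1 of 35 at P24 (-0.18, highest other 0.168). At P10 and at P24, 1 split each could only be fitted without a sex term.

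For age, the real grouping alone among 35 splits called as many genes from P4 to P10 (2050, highest other 328), from P10 to P24 (2140, highest other 6) and from P4 to P24 (2913, highest other 2), that is 1 of 35 each time. For lists the numbers were 3 of 35 from P4 to P10 (18 lists, highest other 19), 1 of 35 from P10 to P24 (15, highest other 14) and 2 of 35 from P4 to P24 (19, highest other 20). Of 100 groupings over all ages 1 called as many as 4034 genes (highest other 1294). For genes whose incision effect differed between ages, 2 of 100 called at least 12 (highest other 15).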
